A study of Mus musculus with 6 samples.

How the data were processed

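Gene expression was measured by RNA sequencing of heart tissue from 6 mice, 3 in the group called Ctrl and 3 in the group called DCM. Per the labels' protocols, libraries were prepared from total RNA with an Illumina TruSeq RNA kit. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program, the annotation release, any filter on genes and the use of strand in counting are not given in the sources used here.

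The deposited table holds 1 row for each of 56980 Ensembl genes and 1 column of values for each of the 6 animals, which match the sample titles by name. The values are estimated (expected) counts as the authors deposited them, judged from the values: 20.6% of the values above 0 were not whole, and the column totals differed. The authors also deposited a mean of the estimated counts for each group, which equalled the mean of its 3 columns to within 3.3e-05 and was used for nothing else. Of the genes, 55438 had a symbol in the table, and the others are named by their Ensembl identifier. Every row names a gene, so no row was left out of the library sizes.

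For testing, the estimated counts were rounded to whole numbers. Genes with too few counts were removed with filterByExpr by group, which left 14003 genes. Libraries were scaled with TMM factors, and DCM was compared with Ctrl in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood F test, 2-sided, with robust dispersion estimates and no covariates. P values were adjusted with the Benjamini-Hochberg method over the genes tested, and a gene was called changed at an adjusted p under 0.05. P values of single genes rest on the spread between these animals, with the estimate for each gene drawn towards those of other genes. Levels are CPM (counts scaled to a common library total) over the TMM-scaled library size, and log2 fold changes are DCM minus Ctrl. The standard error of a log2 fold change was taken as its size divided by the square root of its F statistic, and 95% intervals used the degrees of freedom of that test. Principal components and correlations between libraries used log2 CPM with a prior count of 2.

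Library totals lay between 17817966 and 22600606 estimated counts, at which 1 count equals 0.0445 to 0.0589 CPM. The ratio and interval given for Cyp1a1 come from an exact binomial interval (Clopper-Pearson, 95%) on the summed counts of the groups and cover counting error only. Gene positions are those of GENCODE M21, 1-based, on the same mouse build.

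The test was first tried on simulated data, in which counts were drawn for the 14003 tested genes and 200 genes were changed in each of 5 draws. It recovered 31.6% of the changes planted at 1.5-fold, 72.2% at 2-fold and 91.8% at 4-fold, and 60 of its 714 calls (8.40%) were false, above the nominal 5%. In 5 separate draws without those changes, a fatty acid gene list was shifted by 0.400 on the log2 scale. It was called in 5 of 5 draws, and 1 of 185 tests of other lists made a call. Each gene was drawn independently, whereas the estimated correlation between genes of the fatty acid list was 0.549 in the data. These draws therefore do not show how often the list test makes false calls when genes move together. For single genes, the data gave 27 calls, against 714 over the 5 draws with planted genes. With fewer calls, an adjusted p under 0.05 needs a smaller p, so recovery in the data may be lower than in the draws.

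Before the data were examined, 24 gene lists and 18 lists of cell type markers were written down. They were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, which asks whether the genes of a list moved relative to all other genes, and a list needed at least 3 tested members; 38 lists met this. Their p values were adjusted together. At the preset correlation these p values treat the genes of a list as nearly independent, so they do not rest on the spread between animals alone. Each list was also tested by camera with an estimated correlation and by fry, which asks whether the members move one way on balance. Fry was also run for change of the members in either direction. Of the symbols in the lists, 1 (Ahsp) matched no row of the table. A list of targets of the aryl hydrocarbon receptor and the pathway assignments in the deposited table were added after the data had been seen.

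The genes named were fixed by rule before the data were examined. Hmox1 is always given. Then, among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1, no overlap between the groups and a symbol that is not a predicted-gene name, the 12 largest positive and the 12 largest negative log2 fold changes are named. For each list up to 3 higher and 3 lower members that passed are named, and where none passed the member with the smallest unadjusted p is given as values. Further called genes and members of lists were chosen as examples after their values had been seen. The value of 1 list member is not reported here.

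The alternatives tried were other scaling factors, DESeq2 1.42.0, limma-voom with and without quality weights, other filters, other dispersion settings, the replicate number as a block, removal of mitochondrial and haemoglobin genes, leaving out each library in turn, and a test against a fold change of 1.2. A correction for GC content and transcript length and a second dispersion setting were added after the data had been seen.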

Results

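Heart tissue was profiled from 6 mice, 3 controls (Ctrl) and 3 with diabetic cardiomyopathy (DCM). The DCM mice ate a high-fat diet with 60% of its energy as fat. At 12 weeks of age they were given streptozotocin, a toxin of the insulin-producing beta cells, at 40 mg/kg on 3 days, and mice with fasting glucose of at least 11.1 mM after 7 days entered the group. Ctrl mice ate normal chow and received the injection buffer. Hearts were taken at 25 weeks of age. DCM mice received both diet and toxin, so a difference between the groups cannot be assigned to either. The labels also name a cultured cell line and smooth muscle cells for the same samples, in conflict with the tissue they state; Myh6, the main cardiac myosin heavy chain, stood at 30945 ± 984 CPM (SD, n = 3) in Ctrl and 28093 ± 976 CPM (SD, n = 3) in DCM. Sex, batch and time of day of collection are not in the labels. Library totals were 22600606, 20432716 and 17817966 counts in Ctrl and 20177263, 17820444 and 18261011 in DCM. The title of the series concerns heme oxygenase (Hmox1) and ferroptosis in this disease, and the design compares DCM with Ctrl.

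DCM hearts held more mRNA of Ucp2, Aox1, Ephx2 and the fatty acid transport genes Slc27a1 and Slc25a20, and less of Cyp1a1, Apln, Rel and Lrrc4b. Of 14003 genes tested, 27 changed, 19 higher and 8 lower in DCM, and 13 of them changed at least 2-fold (7 higher, 6 lower). At an unadjusted p under 0.05 989 genes were higher and 1002 lower. Ucp2, a mitochondrial inner membrane carrier (chromosome 7, 100493337 to 100502020), rose from 58.0 ± 6.14 CPM (SD, n = 3) to 146 ± 28.1 CPM (SD, n = 3), a log2 fold change of 1.33 ± 0.14 (SE) with adjusted p = 0.0119 in edgeR's quasi-likelihood test. Cyp1a1, a cytochrome P450 induced by aryl hydrocarbon receptor ligands (chromosome 9, 57687928 to 57703824), fell from 10.8 ± 4.94 CPM (SD, n = 3) in Ctrl to 3 counts in the 3 DCM libraries together, against 659 in Ctrl. The Ctrl level was 199.8 times the DCM level, with a counting interval of 68.1 to 971 (adjusted p = 0.0166). The DCM counts of Cyp1a1 lay in DCM replicate 1 alone (0.144 CPM, against 0 in DCM replicates 2 and 3), so the size of this ratio rests on that library, and the fitted log2 fold change ran from -10.69 to -6.98 over the alternatives. Without Ctrl replicate 3 edgeR called 0 genes (1676 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 132, and without DCM replicate 2 edgeR called 2; it called 13 without Ctrl replicate 1 (6 higher, 7 lower), 138 without Ctrl replicate 2 and 14 without DCM replicate 3. With 6 libraries DESeq2 called 336 genes and limma-voom 10, and edgeR without composition factors called 55 (33 higher, 22 lower).

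The other genes that rose most were Amph, Hspa1b, Rasgef1b, Banp, Lgals4, Acsm5, Vwa8, Ephx2, Slc27a1, Cyp4b1 and Aox1. Amph, an endocytosis adaptor (chromosome 13, 18948205 to 19150921), had a log2 fold change of 1.83 ± 0.27 (SE), from a low level of 1.37 ± 0.395 CPM in Ctrl and 4.86 ± 0.937 CPM in DCM. Hspa1b, an inducible heat shock protein 70 (chromosome 17, 34956436 to 34959238), changed by 1.57 ± 0.19 (adjusted p = 0.0119); its near-identical copy Hspa1a stood at 1.41 ± 0.32 (adjusted p = 0.121), and the split of reads between the copies is uncertain. Rasgef1b (chromosome 5, 99217426 to 99729065) and Banp (chromosome 8, 121949750 to 122029258) changed by 1.43 ± 0.20 and 1.35 ± 0.17. Lgals4, a galectin (chromosome 7, 28833854 to 28841708), changed by 1.19 ± 0.15. It begins 1607 bases past the end of Ech1 on the same strand, and Ech1 was 61.6 times as abundant, so its count is uncertain. Acsm5, a mitochondrial acyl-CoA synthetase (chromosome 7, 119519463 to 119545551), changed by 1.08 ± 0.17, and Vwa8, a mitochondrial ATPase (chromosome 14, 78849052 to 79202310), by 0.94 ± 0.15. Vwa8 overlaps a predicted gene on the other strand, which stood at 0.0187 of its level. That gene stood at 10.5 CPM in Ctrl and 6.77 CPM in DCM, while Vwa8 rose from 321 to 616 CPM. These values argue against the overlap as the source of the rise. Ephx2, soluble epoxide hydrolase (chromosome 14, 66084374 to 66124500), rose from 266 ± 23.9 to 505 ± 94.0 CPM. Cyp4b1, a fatty acid hydroxylase of the cytochrome P450 family (chromosome 4, 115624725 to 115647723), changed by 0.89 ± 0.13. Aox1, aldehyde oxidase (chromosome 1, 58029931 to 58106413), rose from 22.7 ± 1.38 to 40.7 ± 1.66 CPM with adjusted p = 0.0119. The remaining genes called higher were Slc25a20, Fndc1, Efnb3, Bcr, Creg1, Agrn and Nfe2l1, with log2 fold changes of 0.50 to 0.78. Without Ctrl replicate 3 the 27 called genes, those that fell included, had adjusted p of 0.0783 to 0.234 in edgeR; without DCM replicate 2 2 kept their call, without Ctrl replicate 1 8, and without DCM replicate 1 or DCM replicate 3 12.

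Among the genes that fell, Scgb1c1, a secretoglobin (chromosome 7, 140845547 to 140846769), changed by -1.76 ± 0.20 on the log2 scale (adjusted p = 0.0119). Lrrc4b, a synaptic adhesion protein (chromosome 7, 44429018 to 44463351), changed by -1.22 ± 0.14. Apln, the peptide ligand apelin made largely by endothelial cells (chromosome X, 48025146 to 48034853), fell from 25.4 ± 4.07 to 11.4 ± 0.804 CPM, a log2 fold change of -1.16 ± 0.14. Epn3, an endocytic epsin (chromosome 11, 94489599 to 94499974), and Rel, an NF-kappa-B subunit (chromosome 11, 23736847 to 23770970), changed by -1.12 ± 0.17 and -1.08 ± 0.17. Doc2g (chromosome 19, 4003313 to 4007005) had the smallest change of the genes called lower, -0.58 ± 0.09. Doc2g overlaps a predicted gene on the same strand, which stood at 0.0449 of its level. That gene stood at 10.2 CPM in Ctrl and 11.5 CPM in DCM, while Doc2g fell from 292 to 195 CPM. These values argue against the overlap as the source of the fall. The noncoding gene E230013L22Rik, which overlaps Rab20 on the other strand and is uncertain for that reason, stood at -0.85 ± 0.13. Each of the 27 called genes had no overlap between the CPM of the groups; chance gives 10% of genes with no overlap, and 20.9% of all tested genes had none.

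**Figure D1:**
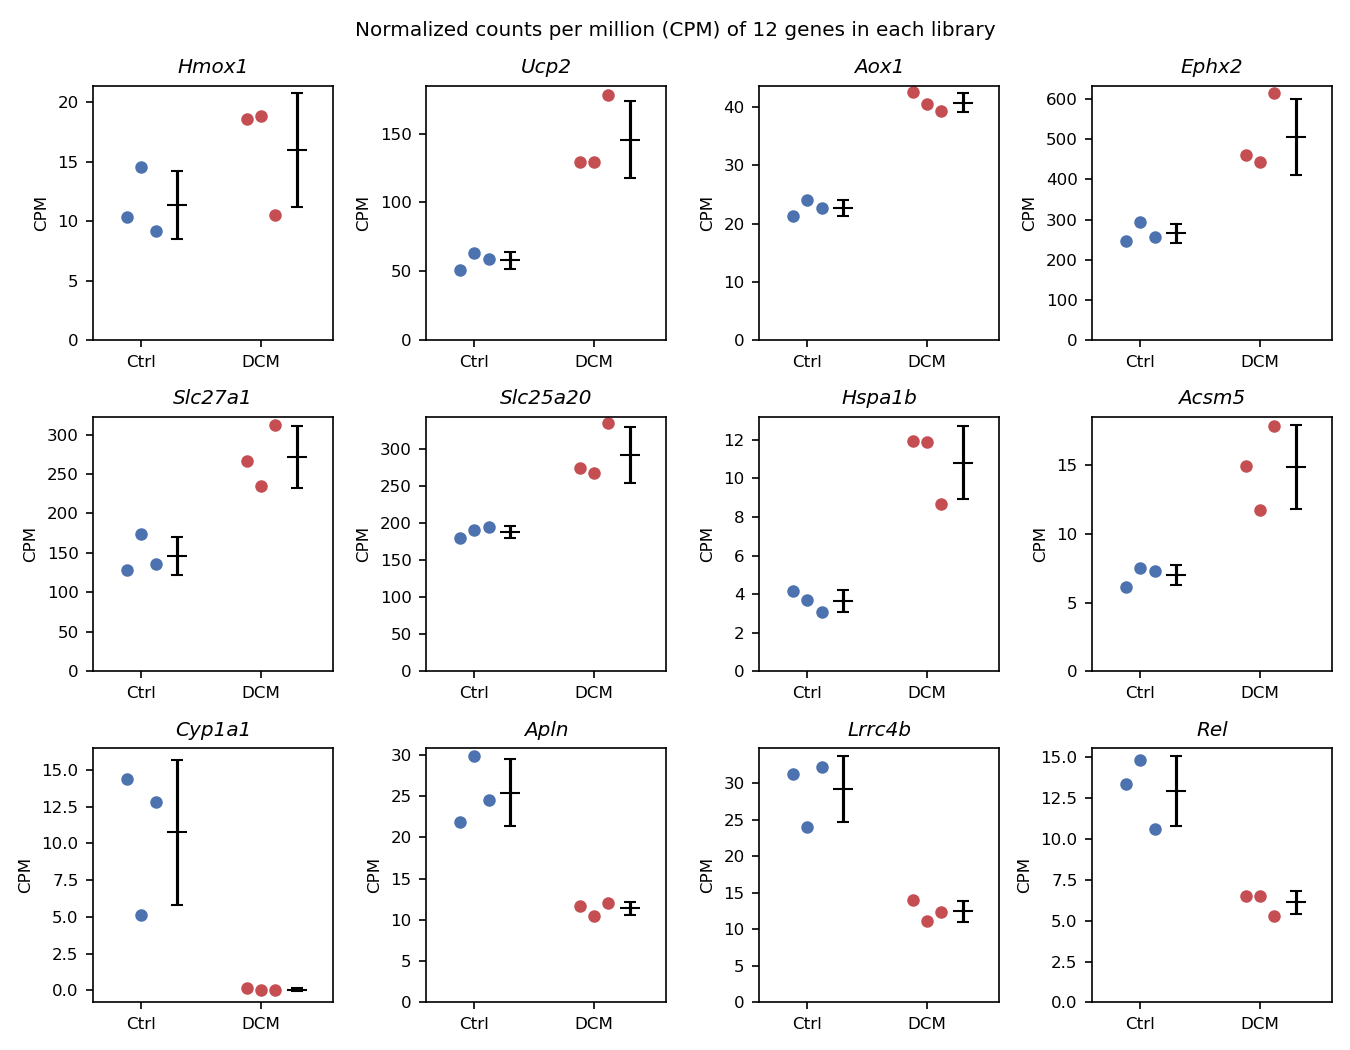
CPM of 12 genes in each library (points; blue Ctrl, red DCM), with the group mean and SD as a black bar at the right of each group; each vertical axis is linear in CPM. Of these genes only Hmox1 has overlapping groups, with DCM replicate 3 at 10.5 CPM; Cyp1a1 lies at or near 0 in the 3 DCM libraries.

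Hmox1, the heme oxygenase that the series is about (chromosome 8, 75093621 to 75100589), did not pass the test. Its levels were 10.4, 14.6 and 9.18 CPM in Ctrl and 18.6, 18.8 and 10.5 CPM in DCM, so that DCM replicates 1 and 2 lay above the Ctrl libraries and DCM replicate 3 among them. The log2 fold change was 0.49 ± 0.25 (SE), with a 95% interval of -0.08 to 1.06 and adjusted p = 0.412 in edgeR. Macrophage markers were lowest in DCM replicate 3, at -0.63 on the log2 scale against the Ctrl mean. Within Ctrl they did not follow Hmox1. They were lowest in Ctrl replicate 2 (-0.30), where Hmox1 was highest, and highest in Ctrl replicate 1 (0.25).

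Of the 34 tested genes of ferroptosis and iron handling, 0 passed over all genes in edgeR (10 at an unadjusted p under 0.05, 2 called by DESeq2 and 0 by limma-voom), and 2 were higher adjusted over the list alone, Lpcat3 and Chac1. Ferroptosis is iron-dependent cell death by lipid peroxidation. Lpcat3, which loads polyunsaturated fatty acids into phospholipids, had the smallest p of the list, with 42.1 ± 6.60 CPM in Ctrl and 60.2 ± 5.27 CPM in DCM, a log2 fold change of 0.52 ± 0.12 and adjusted p = 0.110. Chac1, a glutathione-degrading enzyme, stood at 0.81 ± 0.20 (adjusted p = 0.121). Gpx4, the lipid peroxidase that restrains ferroptosis, stood at 0.08 ± 0.11, with a 95% interval of -0.17 to 0.33. The ferritin genes Fth1 and Ftl1 stood at 0.07 ± 0.09 and 0.40 ± 0.15, the iron exporter Slc40a1 at 0.59 ± 0.21 and Acsl4 at -0.30 ± 0.26. The transferrin receptor Tfrc ranged from 22.2 to 127 CPM within Ctrl alone. The list as a whole was not called by camera (median 0.07, adjusted p = 0.207), nor were the 17 genes of heme synthesis and breakdown (median -0.02, adjusted p = 0.676), where Ppox had the smallest p at 0.36 ± 0.14. Fry for change in either direction called the ferroptosis list (adjusted p = 0.0431) but not the heme list (adjusted p = 0.157). The ferroptosis median was 0.025 without Ctrl replicate 1, 0.029 without Ctrl replicate 3 and 0.088 without Ctrl replicate 2. The heme median was 0.00401 without Ctrl replicate 2.

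Genes of fatty acid oxidation and PPAR-alpha targets, 41 tested, rose together relative to the other genes (median log2 fold change 0.44, camera adjusted p = 5.4e-24). The call was lost when the correlation was not preset (adjusted p = 0.536 with an estimated correlation). At the preset one the list was also called in 7 of the 9 other splits of the 6 libraries into groups of 3. Those splits keep part of any difference between DCM and Ctrl, so they are not unrelated groupings. That kept part may not account for every call, since in 1 called split the median was higher on the side with fewer DCM libraries. Slc25a20, the carnitine-acylcarnitine carrier of mitochondria (chromosome 9, 108662088 to 108684641), and Slc27a1, a fatty acid transport protein (chromosome 8, 71568882 to 71587302), passed over all genes in edgeR, at 0.63 ± 0.10 (adjusted p = 0.0404) and 0.89 ± 0.14 (adjusted p = 0.0404). Neither kept its call without Ctrl replicate 3, where no gene had an adjusted p under 0.0783 among those called. Adjusted over the list alone, 27 members were higher and 1, the lipoprotein lipase gene Lpl, was lower. Examples chosen after their values were seen are the beta-oxidation enzymes Ech1 at 0.91 ± 0.15, Decr1 at 0.79 ± 0.15 and Acadvl at 0.58 ± 0.11, and Cpt2 at 0.62 ± 0.12. Acot1 and Acot2, thioesterases with near-identical copies and so uncertain, stood at 1.92 and 1.35. Pdk4, the kinase that inhibits pyruvate dehydrogenase, was uneven within Ctrl, at 185, 1442 and 629 CPM.

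The ketone body list was not called (median -0.04 and mean 0.25, which differ in sign, camera direction down, adjusted p = 0.774). Oxct1, which activates acetoacetate in ketone body use, had the smallest p of the list, at -0.72 ± 0.16 (adjusted p = 0.110). Adjusted over the list alone, 2 of 7 members were higher and 1 was lower. The ketone median was 0.04 without Ctrl replicate 2 and 0.03 without DCM replicate 1. It was -0.18 without Ctrl replicate 1 and -0.16 without Ctrl replicate 3. Genes of glucose uptake, glycolysis and insulin signalling had a median of -0.08 (adjusted p = 0.188, 0.0113 to 0.759 over the alternatives, the lowest without Ctrl replicate 1). With a correction for GC content and length, camera gave an adjusted p of 0.0329. The glucose median ran from -0.10 to -0.03 over the alternatives. Pfkfb1 stood at 0.74 ± 0.17 and the insulin-regulated glucose transporter Slc2a4 at -0.29 ± 0.11. In this list 1 member was higher and 2 were lower adjusted over the list alone. Lipogenesis and cholesterol synthesis had a median of -0.17 (adjusted p = 0.192, 0.0320 to 0.536 over the alternatives, the lowest with a correction for GC content and length), with Lpin1 at -0.42 ± 0.11, and 1 member higher and 1 lower adjusted over the list alone. Nuclear oxidative phosphorylation genes, 75 tested, had a median of -0.06 (adjusted p = 0.207, 0.0256 to 0.871 over the alternatives, with 0.0463 without DCM replicate 1 and 0.0256 without DCM replicate 3), with Sdhc at 0.29 ± 0.10 and 0 members passing over all genes or the list alone in edgeR (4 at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by limma-voom). Their median was 0.01 without DCM replicate 2. Mitochondrially encoded genes had a median of 0.13 (adjusted p = 0.380, 5.6e-06 to 0.840 over the alternatives, with 0.0298 without Ctrl replicate 1 and the lowest with a correction for GC content and length, where the median was 0.33). Their median was -0.02 without Ctrl replicate 2 and -0.00269 without DCM replicate 3, and mt-Nd2 stood at 0.25 ± 0.13. Nuclear copies of mitochondrial genes also took counts, so these values are uncertain.

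NRF2 targets and antioxidant enzymes, genes of the defence against oxidants, rose relative to other genes (median 0.12, camera adjusted p = 3.0e-04). The call was lost with an estimated correlation (adjusted p = 0.536 with an estimated correlation). Of 40 members, Aox1 passed over all genes in edgeR and 7 were higher adjusted over the list alone, with catalase (Cat) at 0.59 ± 0.14, extracellular superoxide dismutase (Sod3) at 0.61 ± 0.12 and Ephx1 at 0.57 ± 0.11. The NRF2 median was 0.18 without Ctrl replicate 2. Muscle atrophy ubiquitin ligases and FOXO targets also rose (median 0.34, camera adjusted p = 3.0e-04, adjusted p = 0.536 with an estimated correlation), with 5 of 11 higher adjusted over the list alone. Its leading members were the transcription factor Klf15 at 0.50 ± 0.09 and the ubiquitin ligase subunit Fbxo21 at 0.56 ± 0.14. Glucocorticoid-induced genes rose (median 0.53, camera adjusted p = 0.00883, adjusted p = 0.536 with an estimated correlation), with 0 members passing over all genes or over the list alone in edgeR (0 at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by limma-voom). Angptl4, a lipoprotein lipase inhibitor, had the smallest p there at 1.98 ± 0.84; the list shares Angptl4 and Pdk4 with the fatty acid list, and its call was lost without DCM replicate 3 (adjusted p = 0.0985; 8.6e-10 to 0.536 over the alternatives). Interferon response genes rose (median 0.16, camera adjusted p = 0.00801, adjusted p = 0.759 with an estimated correlation), with 0 of 38 members passing over all genes or the list alone in edgeR (7 at an unadjusted p under 0.05, 2 called by DESeq2 and 0 by limma-voom), Irf7 at 0.89 ± 0.22 and Oas2 at 1.23 ± 0.29. That call was lost without Ctrl replicate 2 (adjusted p = 0.697) and without DCM replicate 2 (adjusted p = 0.517; 1.3e-07 to 0.759 over the alternatives). The interferon median was 0.25 without Ctrl replicate 1, 0.05 without Ctrl replicate 2, 0.30 without Ctrl replicate 3, 0.27 without DCM replicate 1 and 0.02 without DCM replicate 2.

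Sarcomere and calcium handling genes fell relative to other genes (median -0.13, camera adjusted p = 3.3e-04, adjusted p = 0.536 with an estimated correlation). Of 34 members 0 passed over all genes in edgeR (9 at an unadjusted p under 0.05, 5 called by DESeq2 and 0 by limma-voom) and 5 were lower adjusted over the list alone. The thin-filament genes Tnnc1 and Tnnt2 stood at -0.40 ± 0.09 and -0.43 ± 0.11, and the ventricular light chain Myl2 at -0.39 ± 0.09, with 7179 ± 296 CPM in Ctrl and 5489 ± 153 CPM in DCM. The cardiomyocyte markers, which overlap this list, also fell (median -0.15, camera adjusted p = 0.00249, adjusted p = 0.536 with an estimated correlation), with 3 of 10 lower adjusted over the list alone. The cardiomyocyte median was -0.09 without DCM replicate 1. The hypertrophy and fetal gene programme was not called (median -0.14, adjusted p = 0.188). Its member with the smallest p was Rcan1 at -0.31 ± 0.09, and the natriuretic peptide genes Nppa and Nppb, which rise in a loaded heart, stood at -1.22 ± 0.49 and -0.91 ± 0.31 without passing (adjusted p = 0.372 and 0.285). Nppa is also an atrial marker, and the mean level of the atrial markers in DCM replicate 3 was -2.99 against the Ctrl mean on the log2 scale, with Nppa at 52.7 CPM there. Myh7, the slow myosin of the fetal programme, stood at -0.14 ± 0.29. Extracellular matrix and fibrosis genes were not called (median above 0, mean below 0, camera adjusted p = 0.857), and 0 of 39 passed over all genes or the list alone in edgeR (7 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom). Their median was -0.05 without Ctrl replicate 2, -0.05 without DCM replicate 1 and -0.03 without DCM replicate 2. It ran from -0.05 to 0.18 over the alternatives. Collagen genes Col1a1 and Col3a1 stood at -0.01 ± 0.10 and -0.14 ± 0.10, Postn at 0.02 ± 0.36 and Timp3, with the smallest p, at 0.36 ± 0.10.

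The endoplasmic reticulum and integrated stress response list divided, with 7 members higher and 6 lower adjusted over the list alone, 0 of 28 over all genes in edgeR (16 at an unadjusted p under 0.05, 9 called by DESeq2 and 0 by limma-voom), and a median of 0.05 (camera adjusted p = 0.359). The median was -0.02 without Ctrl replicate 1, and it ran from -0.02 to 0.15 over the alternatives. The folding chaperones Hspa5, Hsp90b1, Calr and Pdia6 were among the lower members, at -0.52 ± 0.10, -0.63 ± 0.15, -0.35 ± 0.09 and -0.37 ± 0.09. Members on the higher side were the amino acid response genes Atf5, Asns and Mthfd2, at 0.49 ± 0.10, 0.85 ± 0.25 and 1.28 ± 0.33. Heat shock proteins were not called (median -0.05, mean 0.15, camera direction up, adjusted p = 0.188, 0.0237 to 0.550 over the alternatives, the lowest without Ctrl replicate 2). Hspa1b passed over all genes, and 3 members were higher and 1 lower adjusted over the list alone, with the co-chaperone Dnaja1 at 0.71 ± 0.17. The heat shock median was 0.03 without Ctrl replicate 2 and 0.00170 without DCM replicate 1. In the circadian clock list 3 members were higher and 2 lower adjusted over the list alone. The list was not called (median 0.12, mean -0.02, camera direction up, adjusted p = 0.435), and its median ran from 0.01 to 0.17 over the alternatives. Arntl, the positive arm of the clock, stood at -1.41 ± 0.27. The clock genes Dbp and Per2 stood at 0.45 ± 0.12 and 0.85 ± 0.26, and Nr1d1, a repressor of Arntl, at -0.20 ± 0.12 (adjusted p = 0.473).

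The remaining gene lists were not called, and 0 of their members passed over all genes or over the list alone in edgeR. Members at an unadjusted p under 0.05 numbered 2 for inflammatory cytokines, 4 for antigen presentation, 1 for immediate early genes, 2 for the cell cycle, 5 for apoptosis and 4 for autophagy. DESeq2 called 1 member each of the inflammatory, antigen, immediate early and apoptosis lists, and limma-voom called 0 in all 6. Inflammatory cytokines and chemokines had a median of 0.05 (adjusted p = 0.435), with Sele at -1.13 ± 0.35. Antigen presentation had a median of -0.05, a mean of 0.01 and a camera direction of up (adjusted p = 0.449, 0.00985 to 0.996 over the alternatives, the lowest without DCM replicate 3), with H2-T23 at 0.54 ± 0.15. Immediate early genes had a median of 0.07, a mean of -0.13 and a camera direction of up (adjusted p = 0.380, 3.8e-10 to 0.986 over the alternatives, the lowest without Ctrl replicate 2), with Ier3 at 0.62 ± 0.18. The cell cycle list had a median of -0.04 (adjusted p = 0.781), with Bub1b at -0.86 ± 0.32. Apoptosis, pyroptosis and p53 targets had a median of 0.03 (adjusted p = 0.676), with Bax at 0.46 ± 0.13. Autophagy and lysosome genes had a median of -2.6e-04, a mean of 0.05 and a camera direction of up (adjusted p = 0.470), with Ctsl at -0.30 ± 0.08. Single libraries set the sign of several of these medians. Antigen presentation stood at 0.03 without Ctrl replicate 1 and 0.14 without DCM replicate 3. Immediate early genes stood at -0.15 without Ctrl replicate 1, -0.05 without Ctrl replicate 3, -0.14 without DCM replicate 2 and -0.06 without DCM replicate 3. Over the alternatives the median ran from -0.25 to 0.14 for antigen presentation and from -0.15 to 0.65 for immediate early genes. The cell cycle list stood at 0.02 without Ctrl replicate 2 and 0.06 without DCM replicate 3, apoptosis at -0.01 without Ctrl replicate 1 and -0.02 without DCM replicate 2 and autophagy at 0.02 without Ctrl replicate 2 and 0.01 without Ctrl replicate 3.

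**Figure D2:**
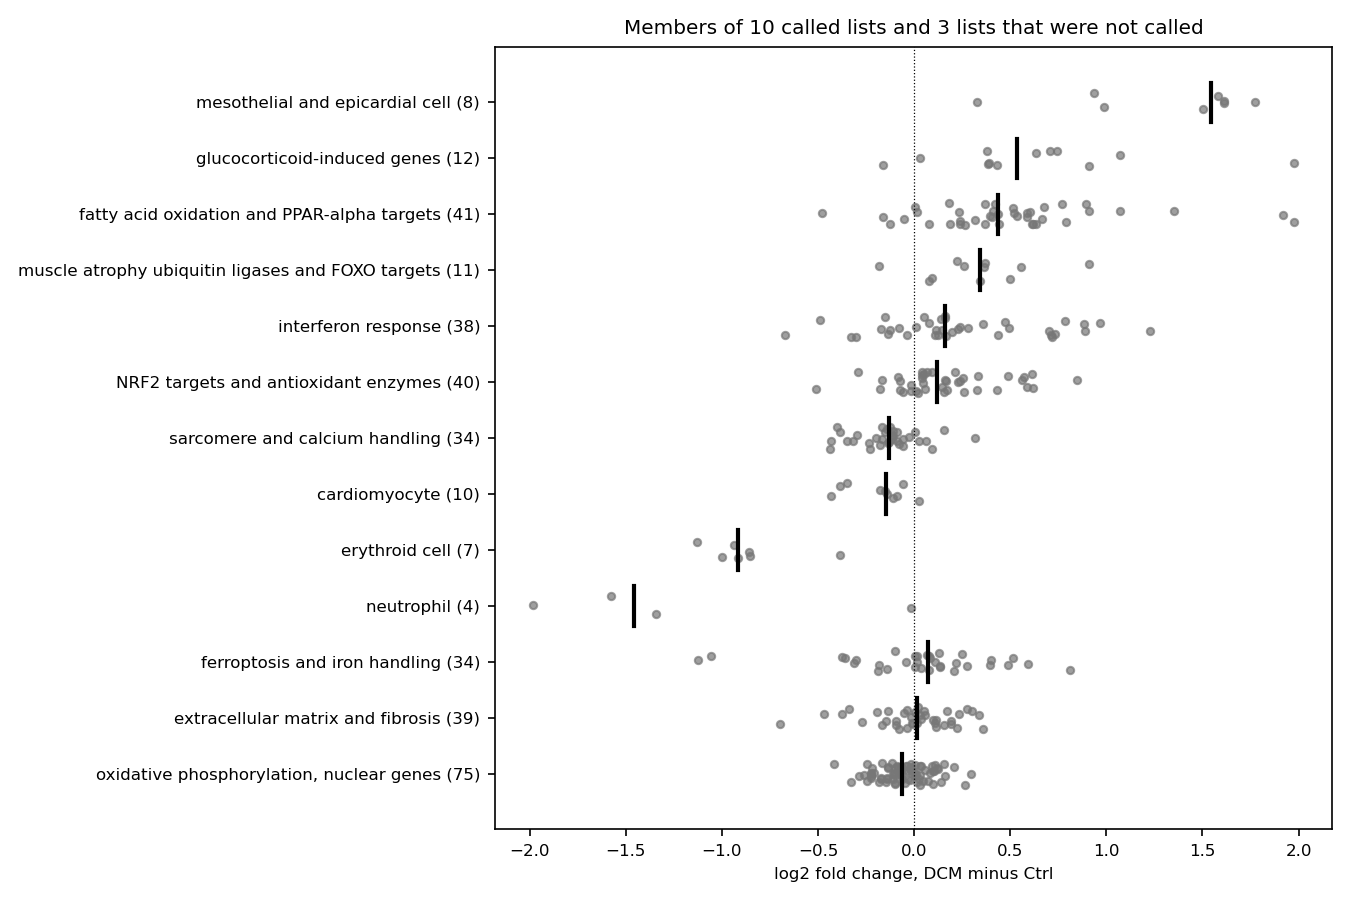
Log2 fold change (DCM minus Ctrl) of each tested member of the 10 called lists and of 3 lists that were not called, with the median as a black bar and the number of members in brackets. The median of the fatty acid oxidation list lies at 0.44 and that of the sarcomere list at -0.13; each of the 10 calls was lost with an estimated correlation.

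Cell type markers differed between single libraries. Mesothelial and epicardial markers, from the outer covering of the heart, rose in DCM (median 1.54, camera adjusted p = 2.8e-06, adjusted p = 0.536 with an estimated correlation), with 5 of 8 higher adjusted over the list alone and Upk3b at 1.77 ± 0.43. Their mean level stood at 1.62, 0.45 and 1.40 above the Ctrl mean on the log2 scale in DCM replicates 1, 2 and 3, while Ctrl replicate 1 stood at 0.53. Erythroid markers fell (median -0.92, camera adjusted p = 0.00247, adjusted p = 0.536 with an estimated correlation), a call lost without Ctrl replicate 2 (adjusted p = 0.0989; 1.4e-08 to 0.536 over the alternatives). The erythroid median was -0.50 without DCM replicate 1 and -1.49 without DCM replicate 3. Bpgm had the smallest p there at -0.39 ± 0.13, and haemoglobin genes took 0.0152% to 0.0588% of counts in DCM and 0.0475% to 0.0959% in Ctrl. Neutrophil markers fell (median -1.46, 4 members, camera adjusted p = 0.0319, adjusted p = 0.536 with an estimated correlation), with S100a9 at -1.98 ± 0.56 and 1 member lower adjusted over the list alone. This call was lost without Ctrl replicate 1 (adjusted p = 0.0957; 9.6e-07 to 0.536 over the alternatives). The neutrophil median was -2.24 without DCM replicate 2. Atrial markers were not called (median -0.25, adjusted p = 0.359). The atrial median was 0.25 without Ctrl replicate 1 and 0.26 without DCM replicate 3, and it ran from -1.12 to 0.26 over the alternatives. The atrial light chain Myl7 ranged from 0.471 CPM in DCM replicate 3 to 70.4 CPM in DCM replicate 1 and from 10.9 to 68.3 CPM in Ctrl.

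The other cell type lists were not called. Adjusted p was 0.188 for fibroblasts (0.0160 to 0.759 over the alternatives, with 0.0192 without Ctrl replicate 1 and 0.0160 without DCM replicate 3), 0.188 for endothelial cells, 0.207 for smooth muscle cells and pericytes (0.0189 to 0.759 over the alternatives, the lowest without DCM replicate 3) and 0.469 for macrophages. Their members with the smallest p were Gsn at 0.46 ± 0.15, Vwf at 0.49 ± 0.15, Acta2 at 0.77 ± 0.28 and Mrc1 at -0.25 ± 0.18. White adipocyte markers had an adjusted p of 0.0826 (0.00530 to 0.996 over the alternatives, with 0.00530 without Ctrl replicate 3, 0.0400 without DCM replicate 3, 0.0461 without composition factors and 0.00787 with a filter at 1 CPM), with Trarg1 at 1.08 ± 0.22 and 2 members higher adjusted over the list alone. Brown adipocyte markers had an adjusted p of 0.192, with Cidea at 0.55 ± 0.13 and 2 members higher adjusted over the list alone. Adjusted p was 0.676 for B and plasma cells with Igkc at 0.62 ± 0.66, 0.676 for Schwann cells with Sox10 at 0.98 ± 0.43, and 0.770 for skeletal muscle with Atp2a1 at 1.57 ± 0.51, where the median of -0.16 differs in sign from the mean of 0.28 and the camera direction of up. The skeletal muscle median was 0.27 without DCM replicate 3. T and NK cells, platelets and thymocytes had too few tested members for a test; Cd4, Pf4 and Satb1 stood at -0.29 ± 0.38, 0.20 ± 0.16 and 0.25 ± 0.12. Lung epithelium had 0 tested members.

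**Figure D3:**
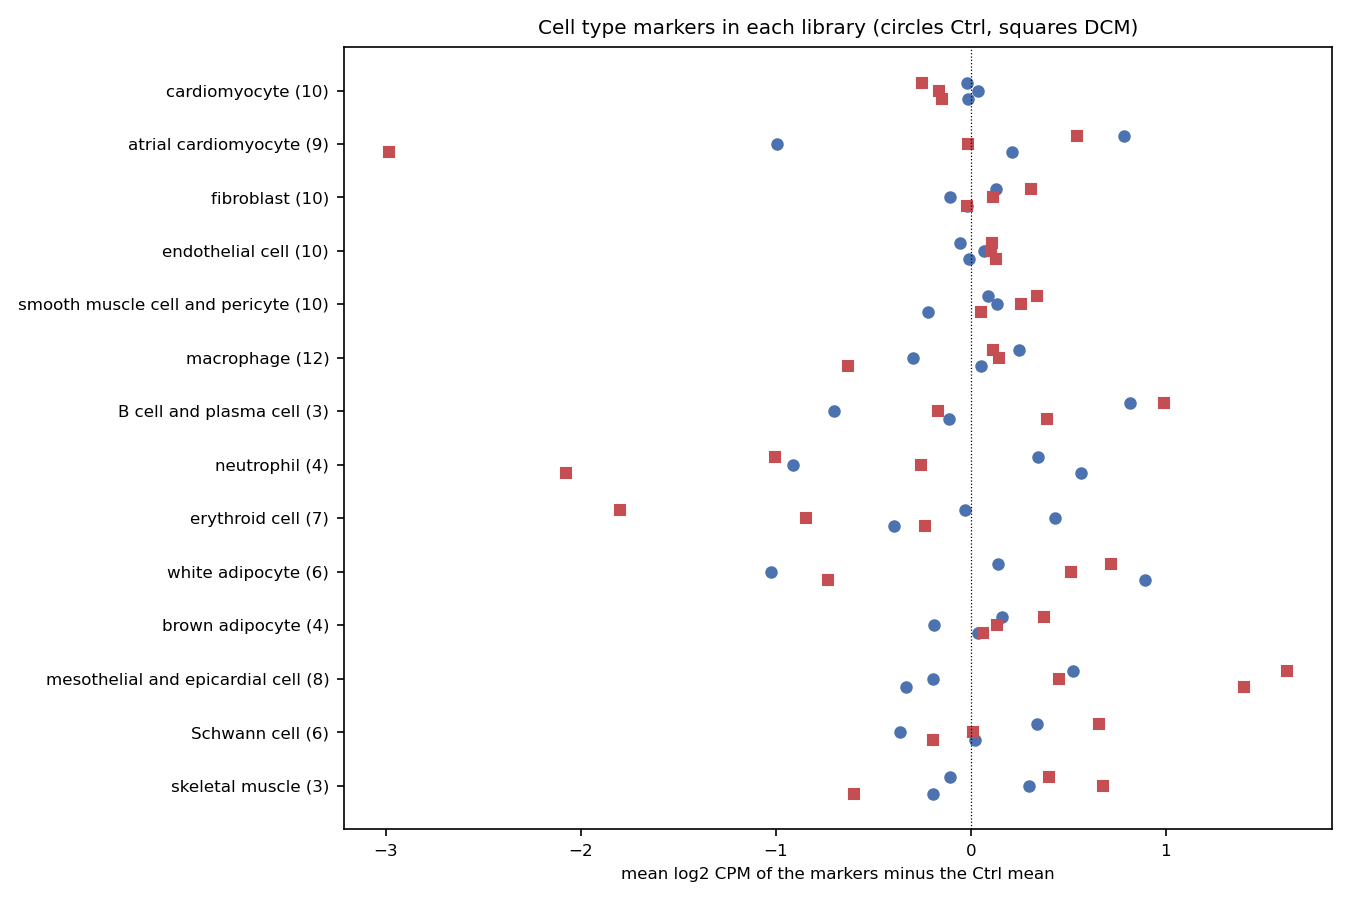
Mean log2 CPM of the markers of each cell type minus the mean of the Ctrl libraries, 1 point per library (blue circles Ctrl, red squares DCM), with the number of markers in brackets. Within DCM atrial markers spread most, down to -2.99 in DCM replicate 3, while the 3 DCM libraries lie below the 3 Ctrl libraries for cardiomyocyte markers.

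Neither the first nor the second principal component alone separated the groups fully. The mean Pearson correlation of log2 CPM was 0.981 between libraries of the same group and 0.978 between groups, across genes, which are not independent replicates. Single pairs ran from 0.971 to 0.985. Ctrl replicates 1 and 2 correlated at 0.974, below the mean between groups. The first principal component held 32.2% of the variance and the second 22.8%. On the first, scores were -34.7, 4.89 and -18.2 in Ctrl and 4.74, 11.2 and 32.2 in DCM. Ctrl replicate 2 thus lay at nearly the score of DCM replicate 1. On the second, scores were -9.91, 37.0 and 6.28 in Ctrl and -17.9, -8.13 and -7.30 in DCM. On both components together the groups lay apart. Counts of each pair of libraries differed by far more than sampling noise, with a chi-square per gene of at least 12.5, so no library was a copy of another. Mitochondrially encoded genes took 18.4% to 23.6% of counts. Nuclear copies of these genes took a further 4.31% to 6.37%, so the split of reads between genes and copies is uncertain. The setting that removed mitochondrial genes left these copies in.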

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

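The correction for GC content and length and the setting legacy=FALSE were chosen after the data had been seen; the other settings were chosen before. The 27 genes changed between DCM and Ctrl became 55 without composition factors (33 higher and 22 lower), 336 with DESeq2, 10 with limma-voom, 265 with quality weights, 709 without a filter on low counts (374 higher and 335 lower), 9 against a fold change of 1.2 and 47 with the correction for GC content and length; the cause of these differences was not tested. Leaving out 1 library at a time gave 0 to 138 genes. Without Ctrl replicate 3 none was called by edgeR (1676 at an unadjusted p under 0.05; 132 by DESeq2), and without DCM replicate 2, 2 were; apart from the smaller number of libraries the cause was not tested. Without Ctrl replicate 3 the Ctrl group was Ctrl replicates 1 and 2, whose correlation of 0.974 was the lowest within a group. The quality weights of limma-voom were lowest for Ctrl replicates 1 and 2 (0.402 and 0.602) and highest for Ctrl replicate 3 (2.57). The called genes kept their direction under each of the 21 settings. None of the 27 had overlapping CPM between the groups, so leaving out a library could hardly turn a direction, and this is no separate support. Of the 27, DESeq2 and the fit without a filter also called 27, limma-voom 8 and the fit without composition factors 26; without robust dispersion estimates 19 genes were called, 16 of them among the 27. The planned setting legacy=TRUE is the default of this edgeR version and moved nothing. The other scaling factors and the CPM filter stayed within 1.5 times. Hmox1 was not called under any of the 21 settings, with log2 fold changes of 0.36 to 0.72 and adjusted p of 0.0516 to 1.00.

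Replicate numbers are shared by the groups. The pairs correlated at 0.119, -0.0336 and -0.0973 in their deviations from the group means, and Ctrl replicate 2 correlated best with DCM replicate 3 (0.159). With so few libraries these correlations cannot tell whether the numbers mark anything shared between the groups. With the replicate block 64 genes were called, 25 of them among the 27, and 11 lists; the neutrophil list lost its call (adjusted p = 0.0720) and the immediate early and white adipocyte lists gained one.

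The 10 called gene lists became 0 with an estimated correlation (0 also at an unadjusted p under 0.05) and 0 with fry (6 at an unadjusted p under 0.05; fry for change in either direction called 14); the cause was not tested. Fry for change in either direction also called lists that camera did not call. These were the ferroptosis, ketone body, glucose, lipogenesis, hypertrophy, circadian clock, endoplasmic reticulum, heat shock and white adipocyte lists. At the preset correlation, leaving out 1 library gave 9 to 14 lists. The mean correlation within and between groups was 0.977 and 0.973 with a prior count of 0.5, and 0.766 and 0.732 over the 500 most variable genes. With 3 libraries per group and 0.0445 to 0.0589 CPM per count, the test on simulated data found 31.6% of 1.5-fold changes, so a change of that size was often not detectable. The share in the data may be lower, since fewer genes were called there and the cutoff on p was stricter.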

Other observations

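The 3 patterns weighed, the pathway test and the tests of other splits for called genes, of mitochondrial or cardiomyocyte share, of endothelial share, of macrophages and of blood were chosen after the result was seen. Pathways were taken from the assignments in the authors' deposited table and tested by camera, with 10 to 300 tested members each. Of 316 pathways 2 were called, both higher in DCM: PPAR signaling (54 genes, median log2 fold change 0.23, adjusted p = 3.6e-07, adjusted p = 0.984 with an estimated correlation) and fatty acid degradation (36 genes, median 0.19, adjusted p = 0.00721, adjusted p = 0.984 with an estimated correlation). With an estimated correlation camera called 0 pathways (2 at an unadjusted p under 0.05).

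The real split gave 27 called genes and the highest of the other 9 splits gave 2; 1 of the 10 splits reached the real value. For the lists, the real split gave 10 calls, the highest other split 18, and 6 of 10 splits gave at least as many. Splits of 6 libraries are too few for a share under 0.05. List calls at the preset correlation were no more numerous for DCM against Ctrl than for 5 of the 9 other splits. Each of those 9 splits puts 2 libraries of one group with 1 of the other. It therefore keeps part of any difference between DCM and Ctrl, and its calls cannot be read as calls from an unrelated grouping. The fatty acid oxidation list was called in 7 of those 9 (lowest adjusted p = 2.7e-12), and its median moved by 0.44 in the real split and by at most 0.33 in the others. In the split of Ctrl replicate 1 and DCM replicates 1 and 2 against the rest, camera called it (adjusted p = 0.0499). There its median was 0.08 higher on the side with fewer DCM libraries. A kept part of the DCM difference would give the other sign, so it may not account for that call.

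The fatty acid oxidation list had a median log2 fold change of 0.44 in DCM, and its call at the preset correlation was lost by camera (adjusted p = 0.536 with an estimated correlation) and by fry (adjusted p = 0.216). A larger share of mitochondrial or cardiomyocyte RNA would raise nuclear oxidative phosphorylation genes by as much, but the fatty acid list stood 0.50 above them on the log2 scale (95% bootstrap interval 0.39 to 0.65); cardiomyocyte markers had a median of -0.15 (adjusted p = 0.536 with an estimated correlation). A bias of GC content or length is argued against by the corrected median of 0.45 (0.37 to 0.55). Both intervals come from resampling the genes of a list, not the animals, and genes of a list can move together. They carry no spread between animals, so both arguments rest on the medians alone. Diet and toxin cannot be separated here, so the hypothesis that the fatty acid supply of the diet drives this difference stays open and untested.

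The Ctrl level of Cyp1a1 was 199.8 times the DCM level. A smaller endothelial share would lower endothelial markers, and their median was 0.086 (0.0094 to 0.15), so the markers as a set did not fall. The test asked for a fall on the scale of Cyp1a1 itself (log2 fold change -7.49), which markers of a whole cell type could hardly reach. It therefore says nothing on a smaller subset of cells or another cell source of Cyp1a1, which were not tested. The intervals given here for marker and target genes come from resampling genes, not animals, and carry no spread between animals. A candidate explanation is lower activity of the aryl hydrocarbon receptor, since chow and purified high-fat diets may differ in its ligands; the 4 other targets tested had a median of -0.14 (-0.40 to 0.47, bootstrap), Cyp1b1 stood at 0.47 and Tiparp at -0.31, so the test decided nothing. Camera gave a p of 0.734 for these targets.

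Hmox1 did not pass the test, and its levels may follow the cells or blood in each piece of tissue. With macrophage markers as a covariate its log2 fold change was 0.50 (95% interval -0.07 to 1.07), and with erythroid markers 0.30 (-0.58 to 1.19), against 0.49 without. With 6 libraries neither interval excludes the values either explanation needs, so these cannot be told apart from a difference between the groups.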
